A study of Mus musculus with 16 samples.

How the data were processed

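The deposited scanner files give intensity values that, per the file headers, Agilent Feature Extraction 10.7.3.1 made with its protocol GE1_107_Sep09 by subtracting background and detrending within each array. No normalization between arrays had been applied to them. The files also hold, per the file headers, raw median intensities of spots and of their local background, and 0/1 flags ("other" values) for well above background, saturation and outliers. The deposited series values are intensity values that had been scaled further. Their MDP columns and their cMoP columns each equal the scanner values times a constant that gives a common 75th percentile (78.2 and 505), and their 32Dcl.3 columns were quantile normalized. The software of that step is not given in the sources used here.

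Per the labels, total RNA was extracted with the RNeasy Micro Kit and labelled with Cy3 by Low Input Quick Amp Labeling. The 32Dcl.3 cells were grown with conditioned medium of WEHI-3B cells, infected with retroviral vectors by spinoculation and collected 3 days later. The array was an Agilent mouse design with 62976 spots, 59305 of them not controls, and 55681 different probes. The file headers name mouse genome build mm9, and gene symbols came from RefSeq accessions listed for GRCm38.p6. Of the probes 26762 matched 1 symbol, 28919 matched none and 0 matched several, giving 20284 symbols. The listed genes without a probe matched to their symbol were Ly6g, Ly6c2, Cd68, Mx1, Mx2, Clec7a, Hbb-b1, Ahsp, Tpsab1 and Hspa1b.

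The array signal was measured first. The 75th percentile of the processed signal was 67.8 to 81.0 on MDP arrays, 455.6 to 567.9 on cMoP arrays and 147.3 to 460.1 on 32Dcl.3 arrays. No probe was saturated, and 102 to 198 spots per array were marked as outliers. Correlations between the 2 arrays of a group were 0.995 to 0.998. MDPs, cMoPs and 32Dcl.3 cells were each on a slide of their own. Within slides, genotype of the MDPs and IRF8 in 32Dcl.3 cells followed the slide column, and C/EBPalpha and the genotype of the cMoPs followed the slide rows. The replicate numbers of the labels did not pair the arrays, as residuals of same-numbered arrays correlated between -0.065 and 0.071.

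Spots marked as outliers were left out, the other spots of a probe were averaged and the values were taken as log2 minus the log2 of the array's 75th percentile. A probe was kept if it was well above background on all arrays of at least 1 of the 4 groups of its system, progenitors or 32Dcl.3 cells. A probe counted as well above background on an array when more than 0.5 of its spots had the flag. The brightest probe stood for a gene with several probes. This left 11963 genes in progenitors and 13337 in 32Dcl.3 cells. Each system was fitted with limma 3.58.1 (R 4.3.3, with the data.table package at version 1.17.8), by lmFit on 4 group means over 8 arrays and eBayes with an intensity trend. The residual degrees of freedom were 4, and the prior ones 6.08 in progenitors and 7.26 in 32Dcl.3 cells. P values were two-sided and adjusted by the method of Benjamini and Hochberg within each comparison, with a threshold of 0.05. The comparisons were the groups against each other, the Irf8KO effect in cMoPs minus that in MDPs, and the IRF8 by C/EBPalpha interaction. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

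A gene not well above background in 1 group was given a bound. On each array of that group its signal was replaced by the higher of its own and that of the faintest probe well above background, so the stated fold is a minimum. The change of such a gene enters list medians as measured, and the medians with genes at their bound are given where they differ in a comparison of 2 groups.

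The 18 gene lists were primary granule proteins, secondary and tertiary granule and late neutrophil genes, granulocyte transcription factors and receptors, monocyte and macrophage genes, dendritic cell genes, MHC class II, interferon-stimulated genes, lysosomal proteases and cystatins, pattern recognition and Fc receptors, stem and early progenitor genes, cell cycle, B cell genes, T and NK cell genes, erythroid genes, megakaryocyte and platelet genes, basophil, mast cell and eosinophil genes, immediate early and heat shock genes, and the C/EBP and IRF families. They were tested with limma's camera at its preset correlation between genes of 0.01 and again with the correlation estimated from the data. P values of lists were adjusted over the 18 lists of a comparison. A call lost with an estimated correlation need not mean correlated genes. In Irf8KO MDPs the basophil list had an estimated correlation of -0.0383, under the preset 0.01. Its unadjusted camera p still went from 7.58e-06 to 0.00904. Sets of the 200 genes that each factor raised most in 32Dcl.3 cells were tested in the same way in the knockouts. Overlaps of all called genes and of those changed at least 2-fold were tested by Fisher's exact test, two-sided, with adjustment over 40 tests.

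Genes were named by a fixed rule. Irf8 and Cebpa were always named. The 6 called genes with the largest change in each direction followed, if well above background on all arrays of both groups and of the same direction in both same-numbered pairs of arrays. The 3 called genes per direction with the largest bound came next, then up to 4 called members of each list that passed or had at least 3 called members. Clone and model names were left out, as were list members picked by the rule but not detected in the groups compared. 1 gene picked by the rule is not reported here, but stayed in the fits and in its list. For the interaction, for the Irf8KO effect in cMoPs minus that in MDPs and for both factors against empty vectors, 4 genes per direction and members of 4 lists were named.

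The groups, comparisons, lists, naming rule and 13 alternatives were chosen before the data were examined. The alternatives were scaling to the array median, quantile normalization, normexp background correction of the mean spot signal (offset 50) with quantile normalization, the deposited series values, no filter on dim probes, only probes well above background on all 8 arrays, the mean of probes, all 16 arrays in 1 fit, only the groups compared, the replicate number as a block, eBayes without trend, a 2-fold threshold and leaving out each array in turn. Another 5 alternatives were added after the data were seen, namely normexp on the median spot signal, all probes with or without a symbol, the 75th percentile over probes detected on all arrays, limma treat at 1.2-fold, and, for lists in the difference between the knockouts and the interaction, dim values raised to the faintest well-above-background signal of their array. Normexp used the median signal because the files have no mean signal column.

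The recovery of known changes was tested on simulated arrays with the fitted spread, with 50 changed genes per size. In Irf8KO and WT MDPs 46, 70, 78 and 100% were recovered at log2 0.25, 0.5, 1 and 2, with 13 false calls among 11963 genes. In the C/EBPalpha and empty vector groups 46, 84, 88 and 100% were recovered, with 11 false calls among 13337 genes. As a share of the calls made, the false calls were far more frequent than as a share of all genes. Nearly all genes were left unchanged in the simulations, whereas 6155 and 10509 were called in these comparisons of the data. The rates therefore need not carry over to the data.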

Results

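Gene expression was measured on 16 single-colour arrays in 8 groups of 2. The sorted cells were mouse bone marrow monocyte and dendritic cell progenitors (MDPs) and the monocyte-restricted progenitors that follow them (cMoPs), each from wild-type (WT) and from Irf8-deficient (Irf8KO) animals. The cultured cells were 32Dcl.3, a myeloid progenitor line, labelled as transduced with empty vectors, with C/EBPalpha, with IRF8 or with both. IRF8 and C/EBPalpha are transcription factors of the monocyte and granulocyte lineages. Probes well above background made up 37.27 to 38.67% of an MDP array, 43.13 to 44.76% of a cMoP array and 49.86 to 56.24% of a 32Dcl.3 array. The number of arrays, 2 per group, limits the precision of every value.

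Changes are differences of log2 signal with the standard error (SE), from 2 arrays per group. The SE rests on a spread shared by all 8 arrays of a system, so a gene has the same SE in MDPs and cMoPs. Replicate arrays differed more in MDPs, with an SD of the difference of 0.284 (WT) and 0.301 (Irf8KO). In cMoPs it was 0.22 and 0.203. The SE is thus likely too small for MDPs and too large for cMoPs. A gene rose or fell when limma's adjusted p was under 0.05, and the adjusted p beside a gene list is that of camera, which compares the list with the other genes. Where a probe was not well above background on either array of 1 group, the change is given as at least N-fold, the bound defined above. Genes detected in neither group compared can still be called, because other groups kept them in the fit, and they count in lists. Scaling alone can move such genes. The undetected Cebpa probe had a processed signal of 3.52 on empty vector array 1 and 3.35 on array 1 of both factors. Its scaled log2 values there were -7.03 and -5.52. Rises of undetected list members in 32Dcl.3 cells can therefore come from the scaling. Scaling each array to its median in place of its 75th percentile moved the median change of all genes from -0.025 to -0.34 in Irf8KO cMoPs, from -0.14 to -0.45 with C/EBPalpha and from -0.096 to -0.75 with both factors. It moved to -0.35 for both factors against C/EBPalpha, -0.78 against IRF8, -0.23 for the difference between the knockouts and -0.40 for the interaction. With the percentile taken over detected probes it was 0.065 with C/EBPalpha, 0.19 with both factors and 0.21 for both against IRF8. In Irf8KO MDPs that median went from -0.024 to -0.12, and with IRF8 alone from -0.031 to 0.0093. Changes smaller than these shifts depend on the scaling.

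The comparison of Irf8KO with WT MDPs asked what the loss of Irf8 changed in the earlier progenitor. Among genes detected on all arrays compared, Mmp8 and Rtp4 had the largest rises and Ly86 and Ctsh the largest falls. Mmp8, the neutrophil collagenase, rose by 5.15 ± 0.12 (SE), the interferon-inducible genes Rtp4 and Samd9l by 4.97 ± 0.15 and 4.25 ± 0.20, and Ddx58, an RNA sensor, by 4.05 ± 0.089. Plagl1, a zinc finger factor, rose by 3.96 ± 0.12 and Cox6a2, a cytochrome oxidase subunit, by 3.80 ± 0.058. Ly86, the partner of the receptor CD180, changed by -8.62 ± 0.16, the lysosomal protease gene Ctsh by -4.59 ± 0.039, the keratin gene Krt18 by -4.25 ± 0.090 and Klf4, a regulator of monocyte development, by -3.91 ± 0.10. Arl5c changed by -4.13 ± 0.11 and Ppfia4 by -3.40 ± 0.23. Oas2, an antiviral enzyme gene, was at least 45.7-fold higher, Klhl30 at least 25.1-fold and Gpr25 at least 16.8-fold. Hba-a2, a haemoglobin gene, was at least 68.2-fold lower, Apba1 at least 47.3-fold and Aif1, a macrophage gene, at least 39.3-fold. Irf8 itself changed by -0.55 ± 0.037 and stayed well above background on the Irf8KO arrays, so the array alone did not check the Irf8KO label. Cebpa rose by 0.43 ± 0.039.

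All 8 genes of the primary granule list rose (median 0.28, adjusted p = 0.000186, and adjusted p = 0.27 with an estimated correlation). Among them were the elastase gene Elane at 0.75, and Gstm1 at 0.97 and Ms4a3 at 0.47, which are not granule protein genes. Of 18 late neutrophil genes 10 rose, such as S100a8 by 3.78 and Wfdc21 by 2.63, and 6 fell, such as the calprotectin gene S100a9 by -1.38 and the granule gene Camp, at least 1.66-fold lower (median 0.57, adjusted p = 0.0273, and adjusted p = 0.452 with an estimated correlation). Pattern recognition and Fc receptor genes moved upward, 16 of 23 rising and 2 falling, with Fcgr3 up 1.13 and Tlr4 up 1.13 (median 0.43, adjusted p = 0.000129, and adjusted p = 0.262 with an estimated correlation). Of 33 interferon-stimulated genes 18 rose and 9 fell, Ifi44 being at least 2.10-fold lower (median 0.39, adjusted p = 0.00559, and adjusted p = 0.32 with an estimated correlation). Among 18 stem and early progenitor genes 9 fell and 3 rose (median -0.33, adjusted p = 0.0247, and adjusted p = 0.32 with an estimated correlation). Eng changed by -1.44 and Meis1, a stem cell regulator, by -1.11. The monocyte and macrophage list went both ways, 10 of 23 rising and 10 falling, with Irf5 at -1.73 and Ms4a6d at 1.61 (median 0.17, mean -0.014, adjusted p = 0.574). Trem1 at 1.34 and Gfi1 at 0.97 were among 5 of 9 granulocyte factors and receptors that rose, while Cebpe was among the 2 that fell at -0.60 (adjusted p = 0.162).

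Markers of other cell types moved with the genotype in MDPs. Of 13 basophil, mast cell and eosinophil genes 11 fell and 1 rose (median -2.66, or -2.12 with genes at their bound, adjusted p = 0.000129, and adjusted p = 0.163 with an estimated correlation). Prg2, an eosinophil granule gene, was at least 32.7-fold lower. Of 11 erythroid genes 8 fell and 1 rose (median -2.24, adjusted p = 0.000701, and adjusted p = 0.32 with an estimated correlation), Hba-a1 being at least 17.1-fold lower. Of 7 B cell genes 5 rose and 1 fell (median 1.79, or 1.30 with genes at their bound, adjusted p = 0.0126, and adjusted p = 0.32 with an estimated correlation), with the pre-B receptor gene Vpreb1 at 3.14 and Rag2 at 2.27. Of 12 T and NK cell genes 7 rose and 1 fell (median 0.30, adjusted p = 0.0318, and adjusted p = 0.32 with an estimated correlation), Il7r being at least 9.58-fold higher. The size of these medians depended on the scaling, the smallest being -1.19 for basophil, -0.82 for erythroid and 0.77 for B cell genes.

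The dendritic cell list had 7 genes up and 3 down of 17, including Itgax at 3.01 (adjusted p = 0.114), and MHC class II 1 up and 3 down of 9 (adjusted p = 0.457). Of 24 lysosomal genes 7 rose and 11 fell, with Ctss, a cathepsin of antigen presentation, at -1.42 (adjusted p = 0.19). Cell cycle genes numbered 6 up and 16 down of 33, such as Ccne1 at -0.93 (adjusted p = 0.119). The C/EBP and IRF families had 7 up and 7 down of 17, with Irf7 at 1.67 (adjusted p = 0.762). Megakaryocyte genes had 2 up and 2 down of 9 (median 0.11, mean -0.20, adjusted p = 0.999), and immediate early and heat shock genes 4 up and 1 down of 15, Fos at 1.33 (adjusted p = 0.101).

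In all, 6155 of 11963 genes passed, 2733 higher and 3422 lower, 459 and 339 of them by at least 2-fold, and 6153 had the same sign in both same-numbered pairs of arrays. Adjusted over the list alone the counts were equal except for 1 more late neutrophil gene lower, 1 more pattern recognition gene higher, and 19 interferon-stimulated genes higher with 10 lower. Without the filter on dim probes the late neutrophil, interferon-stimulated and T and NK cell calls ended (adjusted p = 0.117, 0.0532 and 0.223), and the lysosomal and cell cycle lists passed, downward (adjusted p = 0.033 and 0.0192). The erythroid median turned to 0.11 among genes well above background on all 8 arrays, and the T and NK call also ended without either Irf8KO array (adjusted p = 0.0549 and 0.0539), as did the B cell call without WT array 1 (adjusted p = 0.108).

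The comparison of Irf8KO with WT cMoPs put the same question to the monocyte-restricted stage. Late neutrophil genes rose, led by Wfdc21 at 5.66 ± 0.072 (SE) and the calprotectin gene S100a8 at 4.40 ± 0.056, and Klf4 and the interferon regulatory factor gene Irf5 fell, by -5.27 ± 0.10 and -4.07. The interferon-inducible genes Rtp4 and Ddx58 rose by 5.17 ± 0.15 and 4.43 ± 0.089, Saa3, an acute phase gene, by 4.81 ± 0.51 and Tmem178 by 4.22 ± 0.044. Rasa4, a Ras regulator, changed by -5.15 ± 0.047, Krt18 by -5.00 ± 0.090, Hba-a2 by -4.63 ± 0.15, Arl5c by -4.57 ± 0.11 and Itga1, an integrin gene, by -4.35 ± 0.13. Ly86 was at least 605.5-fold lower, Aif1 at least 70.2-fold and Apba1 at least 63.97-fold. Oas2 was at least 44.6-fold higher, Armc3 at least 19.7-fold and Ednra, an endothelin receptor gene, at least 16.3-fold. Irf8 changed by -1.48 ± 0.037 and Cebpa rose by 0.88 ± 0.039.

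Of 18 late neutrophil genes 17 rose and 1, Ifitm6, fell (median 2.65, adjusted p = 1.09e-11, and adjusted p = 0.169 with an estimated correlation), among them Chil3 by 4.10, S100a9 by 3.82 and Camp by 2.46. All 8 primary granule genes rose (median 0.67, adjusted p = 4.74e-06, and adjusted p = 0.169 with an estimated correlation), with Gstm1 at 1.55 and Serpinb1a at 1.21. Gfi1 at 2.18 and Cebpe at 1.79, regulators of granulocyte maturation, were among 5 of 9 granulocyte factors that rose, the list median being 0.29 and turning to -0.023 when arrays were scaled to their median (adjusted p = 0.0204, and adjusted p = 0.274 with an estimated correlation). Of 33 interferon-stimulated genes 22 rose and 7 fell, Rtp4 among the former (median 0.60, adjusted p = 5.7e-05, and adjusted p = 0.169 with an estimated correlation). Pattern recognition and Fc receptor genes had 11 up and 3 down of 23, including Clec5a at 2.23 and Tlr4 at 1.55 (median 0.37, adjusted p = 0.0141, and adjusted p = 0.274 with an estimated correlation). Cell cycle genes fell together, 29 of 33 with 1 rising (median -0.38, adjusted p = 8.67e-09, and adjusted p = 0.127 with an estimated correlation), such as the cyclin gene Ccne1 by -0.78 and the mitotic kinase gene Plk1 by -0.69.

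Of 23 monocyte and macrophage genes 10 fell and 5 rose, Pou2f2 at -2.29 and the chemokine receptor gene Cx3cr1 at -1.95 (median -0.033, mean -0.64, adjusted p = 0.19). Lysosomal genes had 9 up and 11 down of 24, with the cathepsin genes Ctsh and Ctss at -3.61 and -3.42 (median 0.025, mean -0.46, adjusted p = 0.484). Stem and early progenitor genes had 5 up and 11 down of 18, including Cd34 at -2.70 (adjusted p = 0.0698). MHC class II had 1 up and 5 down of 9, H2-DMa, a peptide-loading gene, at -1.97 (adjusted p = 0.29), and the dendritic cell list 4 up and 6 down of 17 (adjusted p = 0.78). T and NK cell genes had 3 up and none down of 12, such as Nkg7 at 1.01 (median 0.35, adjusted p = 0.0408, and adjusted p = 0.36 with an estimated correlation). Other cell markers did not pass in the scaling used. Erythroid genes had 1 up and 5 down of 11 (adjusted p = 0.101), basophil genes 4 up and 4 down of 13 (median -0.086, camera direction up, adjusted p = 0.767) and B cell genes 4 up and 2 down of 7 (adjusted p = 0.304). Megakaryocyte genes had 2 up and 3 down of 9 (median 0.30, mean -0.10, adjusted p = 0.831), immediate early and heat shock genes 8 up and 4 down of 15 (adjusted p = 0.19), and the C/EBP and IRF families 6 up and 4 down of 17 (adjusted p = 0.195).

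In this comparison 6472 of 11963 genes passed, 2746 higher and 3726 lower, 581 and 440 by at least 2-fold, each with the same sign in both pairs of arrays. Adjusted over the list alone, counts differed for granulocyte factors (6 higher), monocyte genes (6 higher, 11 lower), pattern recognition genes (4 lower), stem genes (12 lower) and cell cycle genes (31 lower). The T and NK call ended under quantile normalization (adjusted p = 0.0755) and without array 2 of the WT or of the Irf8KO cells (adjusted p = 0.0502 and 0.0642). Without the filter on dim probes erythroid, monocyte and stem genes passed downward (adjusted p = 0.0313, 0.0482 and 0.0482), and by array median stem genes passed downward and B cell genes upward (adjusted p = 0.0289 and 0.0451).

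**Figure D1:**
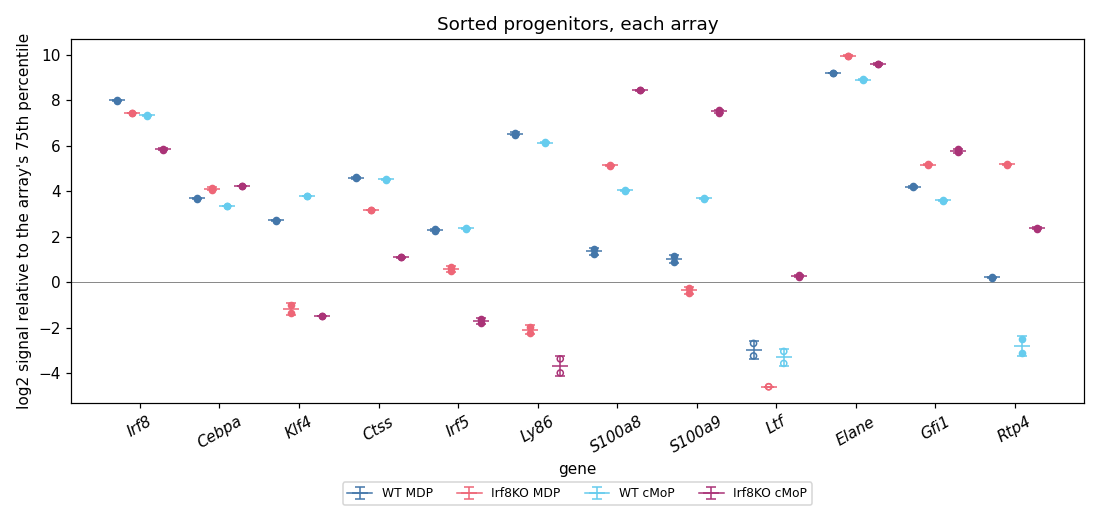
Signal of 12 genes on each array of sorted progenitors, as log2 relative to the array's 75th percentile. Points are single arrays (open where the probe was not well above background on both arrays of the group), bars are the mean ± SD of 2 arrays, and S100a9 was lower in Irf8KO than WT MDPs (-1.38) but higher in Irf8KO than WT cMoPs (3.82).

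Whether the loss of Irf8 acted differently at the 2 stages was tested as the change in cMoPs minus the change in MDPs. Stage coincided with slide and with whether Xist or Y-linked transcripts were detected, so an effect of stage cannot be told apart from theirs. The late neutrophil gene S100a9 differed by 5.20 ± 0.12 (SE), having fallen in Irf8KO MDPs and risen in Irf8KO cMoPs. Wfdc21 differed by 3.04 ± 0.10, Mogat2, a lipid enzyme gene, by 2.48 ± 0.11 and Cebpe by 2.39 ± 0.063. The integrin gene Itgb7 differed by -3.44 ± 0.058, S100a4 by -3.27 ± 0.080, Plxnb2 by -3.11 ± 0.10 and Cox6a2 by -3.02 ± 0.082. Irf8 differed by -0.93 ± 0.052 and Cebpa by 0.45 ± 0.055, the latter call ending when arrays were scaled to their median (adjusted p = 0.0945).

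Among 18 late neutrophil genes 15 differences were positive and 2 negative (median 1.32, adjusted p = 1.61e-12, and adjusted p = 0.132 with an estimated correlation), and primary granule genes 5 positive of 8 (median 0.32, adjusted p = 0.000619, and adjusted p = 0.217 with an estimated correlation). Monocyte and macrophage genes had 14 negative and 2 positive of 23 (median -0.52, adjusted p = 1.04e-05, and adjusted p = 0.0838 with an estimated correlation), such as Cx3cr1 at -2.87 and Irf5 at -2.34. Cell cycle genes had 16 negative and 2 positive of 33 (median -0.24, adjusted p = 2e-04, and adjusted p = 0.132 with an estimated correlation). Basophil, mast cell and eosinophil genes had 11 positive and none negative of 13 (median 2.23, adjusted p = 4.64e-10, and adjusted p = 0.0404 with an estimated correlation). In 9 of the 13 a group was dim, and with dim values raised to the faintest detected signal the median was 1.78 (adjusted p = 1.66e-11, and adjusted p = 0.052 with an estimated correlation). Erythroid genes had 4 positive of 11 (median 0.73, adjusted p = 0.00339, and adjusted p = 0.297 with an estimated correlation), a call that ended among genes well above background on all 8 arrays. Interferon-stimulated genes had 9 positive and 2 negative of 33, with a median of 0.22 that turned to -0.0061 by array median (adjusted p = 0.0154, and adjusted p = 0.297 with an estimated correlation), and that call ended without WT MDP array 1 (adjusted p = 0.0684) and with dim values raised (median 0.067, adjusted p = 0.0624). The other 11 lists did not pass.

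The difference passed for 2980 genes, 1390 positive and 1590 negative, with 4465 at an unadjusted p under 0.05. Adjusted over the list alone the counts were 16 positive late neutrophil, 16 negative monocyte, 10 positive interferon-stimulated, 4 positive and 17 negative cell cycle, 5 negative MHC class II and 12 positive basophil genes. Many changes were shared between the stages. At 2-fold or more, 271 genes were higher in both knockouts where 22.3 would be shared by independent sets (Fisher's exact test, two-sided, adjusted p = 2.38e-256 over 40 tests) and 200 were lower in both against 12.5 (adjusted p = 9.96e-213). Across the 11963 genes the changes correlated with Pearson's r = 0.682 and Spearman's rho = 0.616, and genes are not independent replicates. Of the genes called in both, 4069 changed in the same direction and 314 in opposite directions. Of the 10 that were opposite and at least 2-fold in both, 4 were detected on all 8 arrays, S100a9, lower in MDPs and higher in cMoPs, and Cd28, Phlda3 and S100a4, the reverse.

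**Figure D2:**
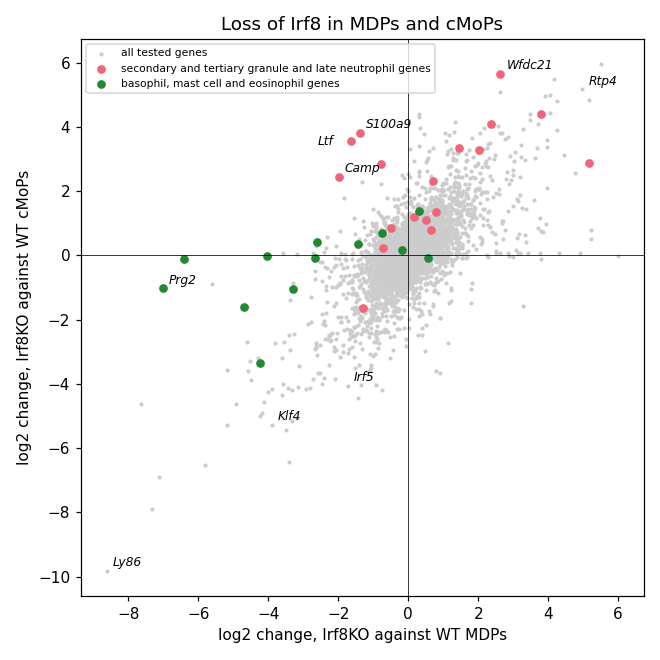
Change (log2) on loss of Irf8 in MDPs (horizontal axis) against cMoPs (vertical axis) for 11963 genes, 1 point per gene without error bars and with undetected values as measured (Ltf in MDPs, for example), with late neutrophil and basophil genes coloured. Late neutrophil genes had a median of 2.65 in cMoPs and 0.57 in MDPs, and basophil genes -0.086 and -2.66.

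The comparison of WT cMoPs with WT MDPs asked what separates the stages in normal animals. Each cell type was on its own slide, and detection of Xist or of Y-linked transcripts also followed cell type. An effect of cell type cannot be told apart from theirs. The median change of all genes was -0.50. Dntt, the lymphoid DNA polymerase gene, changed by -5.20 ± 0.093 (SE) and Flt3, the cytokine receptor of early progenitors, by -4.37 ± 0.051. Ear2, Angpt1, Rab37 and Prss34 changed by -3.96, -3.85, -3.65 and -3.55. Ermn rose by 5.58 ± 0.099, Pnma2 by 5.46 ± 0.088 and Trpm1 by 4.97 ± 0.17, and the adaptor gene Gab3 by 4.71. Akap7 rose by 4.56 on its brightest probe, its 3 probes ranging from -1.12. The X-inactivation transcript Xist was at least 12.1-fold lower in cMoPs, and the Y-linked genes Eif2s3y and Ddx3y at least 47.7-fold and 22.3-fold higher.

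Interferon-stimulated genes were lower in cMoPs, 31 of 33 falling and 2 rising, such as Rtp4 by -3.02 and Oasl2 by -2.40 (median -1.16, or -1.14 with genes at their bound, adjusted p = 0.0166, and adjusted p = 0.478 with an estimated correlation). Of 18 late neutrophil genes 8 rose and 8 fell, with Camp at 3.09 and S100a8 at 2.68. Their median was -0.080, their mean 0.52 and their camera direction up (adjusted p = 0.0166, and adjusted p = 0.478 with an estimated correlation), and the median turned to 0.36 under quantile normalization. That call ended with the percentile over detected probes (median 0.40, adjusted p = 0.0629) and with the deposited series values (adjusted p = 0.391). Stem and early progenitor genes had 17 down and 1 up of 18, including Sox4 at -2.11 (adjusted p = 0.0558), and basophil genes 12 down and 1 up of 13 (adjusted p = 0.249). Under quantile normalization both passed (adjusted p = 0.0026 and 0.0257), as did granulocyte factors and monocyte genes (adjusted p = 0.00214 and 0.0136). Primary granule genes passed there too, upward, their median turning from -0.58 to 0.20 (adjusted p = 0.0257), and the monocyte median turned from -0.16 to 0.21. None of the other 14 lists passed in the scaling used. Cebpa differed by -0.33 ± 0.039 and Irf8 by -0.66 ± 0.037, values within the range that scaling moved. The test passed for 9736 of 11963 genes, 1956 higher and 7780 lower. Under quantile normalization the median of all genes was -0.20, and with the percentile taken over detected probes only it was -0.025.

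C/EBPalpha against empty vectors in 32Dcl.3 cells asked what that factor changes alone. Neutrophil granule genes rose together. Ltf, the lactoferrin gene, rose by 7.88 ± 0.049 (SE), Ngp by 6.73 ± 0.035, Mogat2 by 8.17 ± 0.065, Prom1 by 7.21 ± 0.12 and the protease inhibitor genes Csta2 and Stfa3 by 6.86 ± 0.034 and 6.62 ± 0.10. Retnlg was at least 3054-fold higher, Mgst1, a glutathione transferase gene, at least 912.5-fold and Mmp8 at least 269.8-fold. The haemoglobin genes Hbb-b2 and Hbb-bt changed by -3.28 ± 0.084 and -3.20 ± 0.042, the Myc family gene Mycn by -3.19 ± 0.091, Spag11b by -3.26 ± 0.16, Hkdc1 by -3.25 ± 0.10 and Acvr1, an activin receptor gene, by -3.09 ± 0.084. Nqo1 was at least 6.28-fold lower, Prdm12 at least 5.58-fold and Bex6 at least 5.37-fold. The probes of Cebpa and Irf8 were not well above background in any 32Dcl.3 group, so the array did not check these labels.

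Of 19 late neutrophil genes 18 rose and none fell (median 5.29, adjusted p = 2.09e-14, and adjusted p = 0.0172 with an estimated correlation). All 8 primary granule genes rose (median 2.93, adjusted p = 1.93e-07, and adjusted p = 0.0482 with an estimated correlation), among them Lyz2, the lysozyme gene, by 6.47 and Elane by 3.60. Granulocyte factors and receptors had 8 up and 1 down of 9, with Il6ra at 3.46, Cebpe at 2.61 and Gfi1 at 2.47 (median 1.17, adjusted p = 0.000186, and adjusted p = 0.0761 with an estimated correlation). Monocyte and macrophage genes had 11 up and 5 down of 19, such as Lyz1 at 5.42 and the perforin-like gene Mpeg1 at 4.10 (median 0.63, adjusted p = 0.00513, and adjusted p = 0.0761 with an estimated correlation). Lysosomal genes had 18 up and 2 down of 23 (median 0.74, adjusted p = 2.35e-06, and adjusted p = 0.0466 with an estimated correlation), for example Ctsd at 1.94. Pattern recognition and Fc receptor genes had 18 up and 4 down of 24, including Fcgr4 at 4.29 and Nod1 at 3.76 (median 0.86, adjusted p = 1.09e-05, and adjusted p = 0.0482 with an estimated correlation). Cell cycle genes fell, 33 of 34 with 1 rising (median -0.94, or -0.92 with genes at their bound, adjusted p = 1.42e-07, and adjusted p = 0.0482 with an estimated correlation), such as Cdc6, a replication licensing gene, by -1.61.

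Interferon-stimulated genes had 22 up and 5 down of 30, Gbp2 being at least 7.59-fold higher (median 0.56, adjusted p = 0.000478, and adjusted p = 0.052 with an estimated correlation). Basophil, mast cell and eosinophil genes had 10 up and 1 down of 14, with Ear2 at least 27.6-fold higher (median 0.62, adjusted p = 0.00513, and adjusted p = 0.0761 with an estimated correlation). MHC class II had 7 up and none down of 10 (median 0.70, adjusted p = 0.0158, and adjusted p = 0.237 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.0698), and H2-Aa and H2-Ab1 were detected in neither group. The C/EBP and IRF families had 8 up and 4 down of 14 with a median of 0.24 that turned to -0.064 by array median (adjusted p = 0.0476, and adjusted p = 0.159 with an estimated correlation), a call that also ended without C/EBPalpha array 2 (adjusted p = 0.0628). Erythroid genes had 3 up and 9 down of 13 (adjusted p = 0.108), passing downward under normexp background correction (median -0.86, adjusted p = 0.0291), without the filter on dim probes (adjusted p = 0.0458) and with the percentile over detected probes (adjusted p = 0.0446). Among the lists that did not pass, stem genes had 5 up and 7 down of 17 with Gata2 at -3.02 (adjusted p = 0.889), dendritic cell genes 6 up and 6 down of 16 (median 0.10, mean -0.039, adjusted p = 0.669), B cell genes 4 up of 6 (adjusted p = 0.129), T and NK genes 5 up and 3 down of 11 (adjusted p = 0.215), megakaryocyte genes 3 up and 4 down of 11 (median 0.11, mean -0.22, adjusted p = 0.89) and immediate early and heat shock genes 3 up and 9 down of 15 (adjusted p = 0.669). The test passed for 10509 of 13337 genes, 4221 higher and 6288 lower, 1498 and 1627 by at least 2-fold, with 10500 of the same sign in both pairs of arrays. Adjusted over the list alone the counts were equal except 3 B cell and 2 megakaryocyte genes higher.

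IRF8 against empty vectors asked the same of the other factor. Antigen presentation and macrophage genes rose: Cd74, the MHC class II invariant chain gene, by 7.08 ± 0.042 (SE), the chemokine gene Ccl17 by 6.40 ± 0.045, the lectin receptor gene Clec4n by 6.23 ± 0.041, Ctss by 5.74 ± 0.057, H2-DMa by 5.63 ± 0.093 and Mpeg1 by 5.51 ± 0.039. H2-Ab1 was at least 556.6-fold higher, the adenosine receptor gene Adora3 at least 90.9-fold and the nucleotide receptor gene P2ry6 at least 80.2-fold. Angpt1 changed by -4.24 ± 0.12, Gata1, the erythroid and mast cell regulator, by -3.23 ± 0.22, Trem3 by -2.94 ± 0.089, the granzyme gene Gzmb by -2.78 ± 0.19, Wfdc21 by -2.64 ± 0.042 and Mycn by -2.60 ± 0.091. Nqo1 was at least 10.6-fold lower and Bicc1 at least 6.55-fold.

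All 10 MHC class II genes rose (median 5.01, 4.03 with genes at their bound and 2.22 at the lowest over scalings, adjusted p = 3.18e-12, and adjusted p = 0.0312 with an estimated correlation), H2-Aa being at least 44.7-fold higher. Lysosomal genes had 18 up and 1 down of 23, the cystatin gene Cst3 at 3.29 and Psap at 2.28 (median 0.54, adjusted p = 4.72e-11, and adjusted p = 0.0286 with an estimated correlation). Monocyte and macrophage genes had 13 up and 3 down of 19, including Csf1r, the macrophage growth factor receptor gene, at 3.61 and Ccl6 at 2.90 (median 0.66, adjusted p = 8.79e-06, and adjusted p = 0.0312 with an estimated correlation). Pattern recognition genes had 18 up and 1 down of 24, such as Tlr6 at 1.98 and Unc93b1 at 1.79 (median 0.75, adjusted p = 2.65e-09, and adjusted p = 0.0312 with an estimated correlation), and interferon-stimulated genes 19 up and 3 down of 30, Gbp3 at 3.51 (median 0.63, adjusted p = 1.4e-05, and adjusted p = 0.0312 with an estimated correlation). Dendritic cell genes had 6 up and none down of 16, with Itgax at 2.55 and Id2 at 2.35 (median 0.37, adjusted p = 0.00231, and adjusted p = 0.0628 with an estimated correlation).

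Granule genes fell with IRF8. Of 8 primary granule genes 7 fell and Lyz2 rose by 2.54, Ctsg at -1.59 and the myeloperoxidase gene Mpo at -1.51 (median -1.19, adjusted p = 0.000163, and adjusted p = 0.0754 with an estimated correlation). Late neutrophil genes had 12 down and 6 up of 19, Ngp at -2.51 and Ifitm6 at 2.89 (median -0.52, adjusted p = 0.00442, and adjusted p = 0.0658 with an estimated correlation). Cell cycle genes fell slightly, 25 of 34 with 1 rising, such as Tyms by -0.39 and Mcm2 by -0.32 (median -0.19, adjusted p = 1.26e-05, and adjusted p = 0.0575 with an estimated correlation). Granulocyte factors went both ways, Il6ra at 4.59 and Gfi1 at -1.28 (median -0.077, mean 0.31, adjusted p = 0.576), as did basophil genes with 2 up and 4 down of 14 (median 0.055, mean -0.38, adjusted p = 0.653). The other 7 lists did not pass. The test passed for 6410 of 13337 genes, 3023 higher and 3387 lower, 476 and 204 by at least 2-fold, all with the same sign in both pairs of arrays. Adjusted over the list alone the counts were equal except for 1 more pattern recognition gene higher and 1 more C/EBP or IRF family gene lower.

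**Figure D3:**
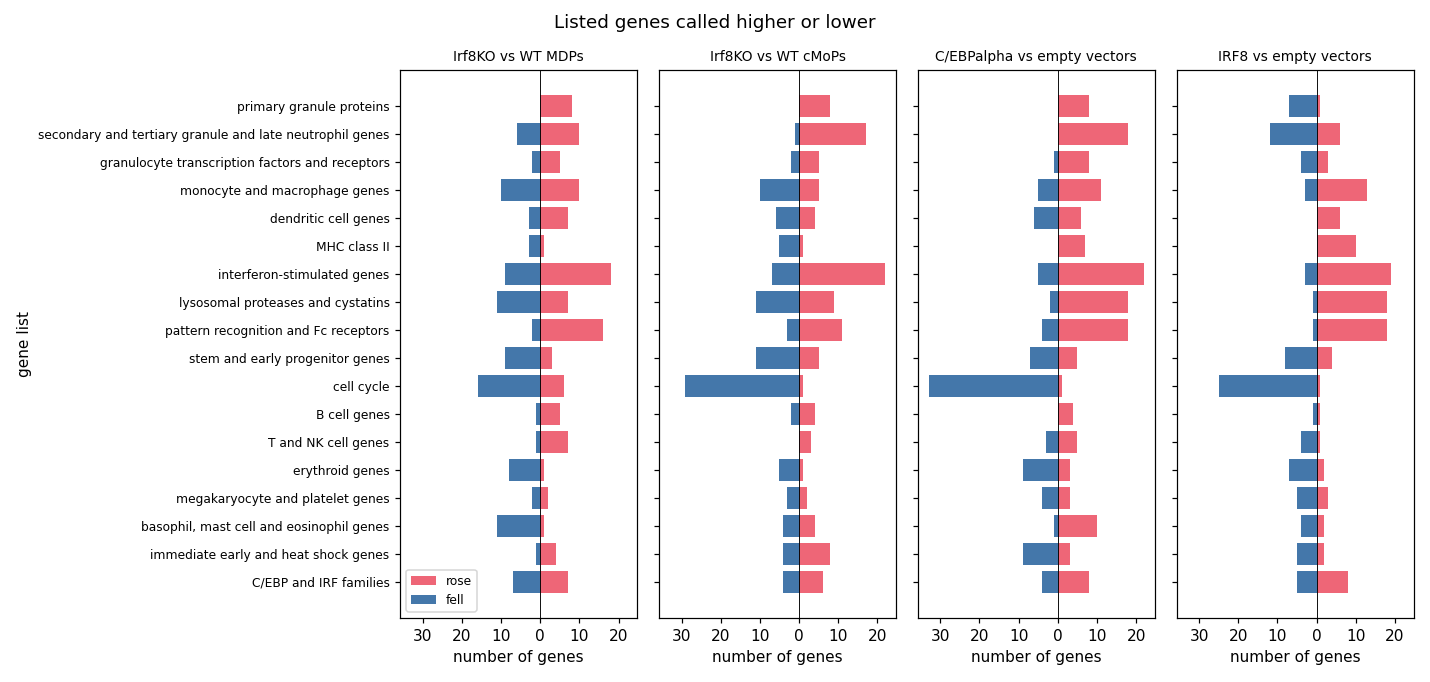
Number of genes of each list that rose (right of 0) or fell (left of 0) in 4 comparisons, for 18 lists, without error bars. Late neutrophil genes rose in Irf8KO cMoPs (17 of 18) and with C/EBPalpha (18 of 19), and all 10 MHC class II genes rose with IRF8.

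Adding IRF8 to C/EBPalpha asked how IRF8 alters the C/EBPalpha programme. Ccl17 rose by 9.72 ± 0.045 (SE), Cd74 by 8.71 ± 0.042, Ctss by 6.49 ± 0.057, Clec4n by 6.09 ± 0.041 and the kallikrein genes Klk1b11 and Klk1b24 by 7.05 ± 0.094 and 6.15 ± 0.10. H2-Eb1 was at least 2665-fold and P2ry6 at least 85.7-fold higher. Trem3 changed by -4.80 ± 0.089, Mycn by -4.32 ± 0.091, Mmrn1 by -4.03 ± 0.081 and Epx, the eosinophil peroxidase gene, by -3.64 ± 0.14.

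All 8 primary granule genes fell, Prtn3 by -2.46 and Elane by -2.35 (median -2.12, adjusted p = 4.57e-06, and adjusted p = 0.0559 with an estimated correlation). Of 19 late neutrophil genes 18 fell and 1 rose, Camp at -3.16 and Ltf at -2.52 (median -2.07, adjusted p = 1.24e-07, and adjusted p = 0.0316 with an estimated correlation). Cell cycle genes fell, 33 of 34, the proliferation marker gene Mki67 by -1.93 and the mitotic kinesin gene Kif11 by -1.88 (median -1.51, adjusted p = 3.64e-15, and adjusted p = 0.0316 with an estimated correlation). All 10 MHC class II genes rose (median 4.07, adjusted p = 1.41e-07, and adjusted p = 0.0559 with an estimated correlation), as did 18 of 23 lysosomal genes with 3 falling, Psap at 3.36 (median 0.65, adjusted p = 1.17e-05, and adjusted p = 0.0407 with an estimated correlation). Dendritic cell genes had 11 up and 3 down of 16, Itgax at 5.22 (median 0.92, adjusted p = 0.00171, and adjusted p = 0.0559 with an estimated correlation). Interferon-stimulated genes had 19 up and 4 down of 30 (median 0.80, adjusted p = 0.000689, and adjusted p = 0.0559 with an estimated correlation). Monocyte genes had 13 up and 5 down of 19, Csf1r at 3.41 (median 0.91, adjusted p = 0.00841, and adjusted p = 0.0915 with an estimated correlation), and pattern recognition genes 16 up and 6 down of 24, Clec4d at 3.37 (median 0.45, adjusted p = 0.00586, and adjusted p = 0.0915 with an estimated correlation). Gfi1 changed by -2.90 and Cebpe by -1.52 in a granulocyte factor list that did not pass (adjusted p = 0.367). Immediate early and heat shock genes had 8 up and 3 down of 15, Junb at 1.85 (median 0.38, adjusted p = 0.0442, and adjusted p = 0.234 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.0854) and without array 1 of both factors (adjusted p = 0.071). The test passed for 9651 genes, 4592 higher and 5059 lower, and over the list alone 7 pattern recognition and 9 basophil genes were lower.

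Both factors against IRF8 alone asked what C/EBPalpha changes when IRF8 is present. Mogat2 rose by 7.44 ± 0.065 (SE), Wfdc21 by 6.52 ± 0.042, Ngp by 6.45 ± 0.035 and Retnlg at least 493.4-fold, while Mycn changed by -4.91 ± 0.091 and Gata2 by -3.42. Late neutrophil genes had 18 up and 1 down of 19 (median 4.33, adjusted p = 1.38e-10, and adjusted p = 0.0332 with an estimated correlation) and primary granule genes 7 up and 1 down of 8, Lyz2 at 3.21 and Mpo at 3.13 (median 1.80, adjusted p = 0.000137, and adjusted p = 0.0889 with an estimated correlation). All 34 cell cycle genes fell, the cyclin gene Ccna2 by -2.91 and Cdc6 by -2.90 (median -2.30, adjusted p = 1.58e-11, and adjusted p = 0.0353 with an estimated correlation). Lysosomal genes (19 up, 3 down of 23, median 0.88, adjusted p = 6.25e-06) and pattern recognition genes (19 up, 2 down of 24, median 1.01, adjusted p = 6.25e-06) rose, with adjusted p = 0.0353 and 0.0454 with an estimated correlation. Interferon-stimulated genes (22 up, 4 down of 30, median 0.75, adjusted p = 0.000213) and monocyte genes (14 up, 3 down of 19, median 0.94, adjusted p = 0.000793) rose, with adjusted p = 0.0509 and 0.0654 with an estimated correlation. MHC class II genes had 7 up of 10, Cd74 at 1.68 (median 1.37, adjusted p = 0.0075, and adjusted p = 0.181 with an estimated correlation). Granulocyte factors had 7 up and 2 down of 9 (median 0.94, adjusted p = 0.00489, and adjusted p = 0.139 with an estimated correlation). Dendritic cell genes had 11 up and 1 down of 16 (median 0.88, adjusted p = 0.0147, and adjusted p = 0.105 with an estimated correlation), a call that ended under quantile normalization (adjusted p = 0.096). The C/EBP and IRF families had 9 up and 3 down of 14 with a median of 0.61 that turned to -0.087 by array median (adjusted p = 0.0143, and adjusted p = 0.105 with an estimated correlation), a call that ended without the filter on dim probes (adjusted p = 0.0943). The test passed for 10961 genes, 4810 higher and 6151 lower.

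Both factors against empty vectors asked what they change together. Cd74 rose by 8.76, Clec4n by 8.74, Mogat2 by 7.90 and Ccl17 by 7.78, while Mycn changed by -7.51, Car12 by -4.26, Tespa1 by -4.17 and Angpt1 by -3.85. Late neutrophil genes had 18 up and 1 down of 19, Ltf at 5.36 and S100a8 at 5.16 (median 3.62, adjusted p = 8.26e-09, and adjusted p = 0.0283 with an estimated correlation). All 10 MHC class II genes rose (median 5.03, or 4.89 with genes at their bound, adjusted p = 3.37e-06, and adjusted p = 0.069 with an estimated correlation) and all 34 cell cycle genes fell (median -2.41, adjusted p = 6.62e-11, and adjusted p = 0.0283 with an estimated correlation). Of 19 monocyte genes 16 rose and 2 fell, Mpeg1 at 7.04 (median 1.09, adjusted p = 4.79e-05, and adjusted p = 0.0371 with an estimated correlation). Primary granule genes had 5 up and 2 down of 8, Lyz2 at 5.76 (median 0.93, adjusted p = 0.0402, and adjusted p = 0.264 with an estimated correlation), a call that ended without the filter on dim probes (adjusted p = 0.128). Granulocyte factors had 6 up and 2 down of 9 (median 0.91, adjusted p = 0.0427, and adjusted p = 0.264 with an estimated correlation), a call that also ended without that filter (adjusted p = 0.138) and with only the groups compared (adjusted p = 0.0533). Interferon-stimulated genes had 25 up and 4 down of 30 (median 1.28, adjusted p = 1.29e-05, and adjusted p = 0.0308 with an estimated correlation), lysosomal genes 20 up and 2 down of 23 (median 1.45, adjusted p = 3.55e-07, and adjusted p = 0.0283 with an estimated correlation) and pattern recognition genes 20 up and 3 down of 24 (median 1.71, adjusted p = 1.32e-06, and adjusted p = 0.0308 with an estimated correlation). Dendritic cell genes (13 up, 2 down of 16, median 1.17, adjusted p = 0.0051) and the C/EBP and IRF families (10 up, 3 down of 14, median 0.84, adjusted p = 0.00653) also passed, with adjusted p = 0.069 and 0.0781 with an estimated correlation. The test passed for 11310 genes, 5074 higher and 6236 lower.

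**Figure D4:**
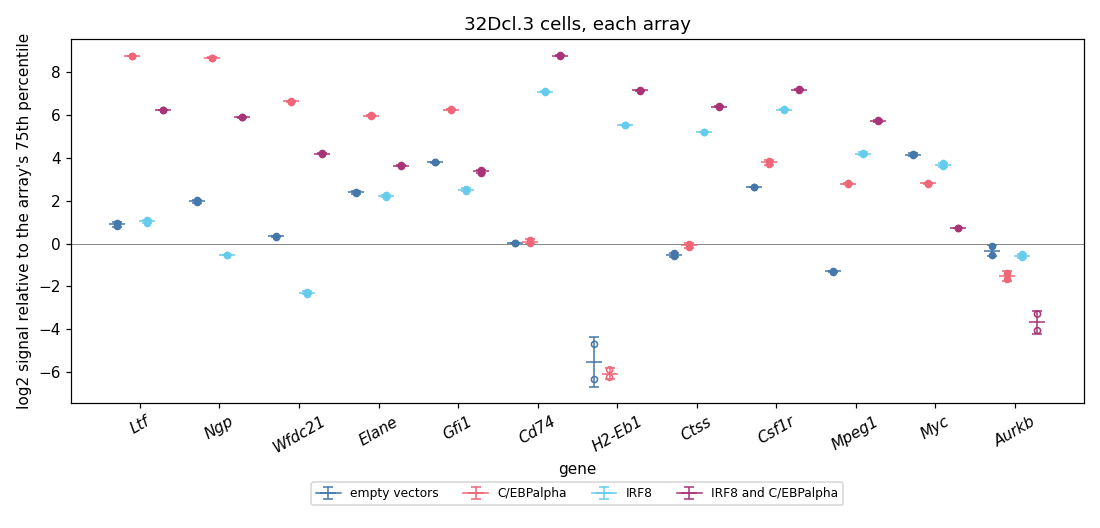
Signal of 12 genes on each 32Dcl.3 array, as log2 relative to the array's 75th percentile. Points are single arrays (open where the probe was not well above background on both arrays of the group) and bars are the mean ± SD of 2 arrays, and the granule gene Ltf was higher with C/EBPalpha (7.88) and lower again when IRF8 was added (-2.52).

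Whether the factors acted independently was tested as their interaction on the log2 scale. Il6, the interleukin gene, exceeded the sum of the single effects by 4.47 ± 0.19 (SE), Ccl17 by 3.32 ± 0.063, Itgax by 2.67 ± 0.11 and Lrrc14b by 2.65 ± 0.12. Lyz2 fell short of it at -3.25 ± 0.041, as did the receptor gene Trem2 at -3.20 ± 0.082, Aldh3b1 at -3.13 ± 0.095 and Pram1 at -2.83 ± 0.045. Late neutrophil genes had 16 negative and 2 positive terms of 19, Ltf at -2.66 and Ifitm6 at -2.26 (median -1.63, adjusted p = 2.19e-07, and adjusted p = 0.0336 with an estimated correlation), primary granule genes 7 negative and 1 positive of 8, Elane at -2.19 (median -1.09, adjusted p = 0.000477, and adjusted p = 0.236 with an estimated correlation) and cell cycle genes 32 negative of 34 (median -1.35, adjusted p = 1.84e-18, and adjusted p = 0.0313 with an estimated correlation). Immediate early and heat shock genes had 9 positive and 3 negative of 15 (median 0.42, adjusted p = 0.0101, and adjusted p = 0.248 with an estimated correlation), a call that ended with the deposited series values (adjusted p = 0.0597). MHC class II had 6 positive and 2 negative of 10, Cd74 at 1.62 (adjusted p = 0.135, but adjusted p = 0.00588 by array median and 0.0218 under quantile normalization), and monocyte genes 8 positive and 10 negative of 19, Mpeg1 at -2.58 (adjusted p = 0.539). Of the 1498 genes that C/EBPalpha raised at least 2-fold, 726 (48.5%) had a negative term and 226 (15.1%) a positive one. Of the 1627 that it lowered 702 (43.1%) had a negative term and 378 (23.2%) a positive one. Arrays simulated without an interaction gave at most 1, so noise in the arrays shared by both tests did not give these counts. The simulation had no error of scaling or background and cannot exclude those. By array median the positive share of all interaction calls went from 42.7 to 9.27%. The interaction passed for 7429 genes, 3175 positive and 4254 negative, with 8061 at an unadjusted p under 0.05. Adjusted over the list alone, 17 late neutrophil terms were negative and 3 MHC class II terms.

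Gene sets from the 32Dcl.3 cells were then tested in the knockouts. Of the 200 genes that C/EBPalpha raised most, 120 were measured in progenitors. In Irf8KO MDPs 74 rose and 22 fell (median 0.50, adjusted p = 4.88e-11, and adjusted p = 0.0198 with an estimated correlation), and in Irf8KO cMoPs 91 rose and 14 fell (median 0.98, adjusted p = 1.77e-19, and adjusted p = 0.0126 with an estimated correlation). Of the 200 genes that IRF8 raised most, 121 were measured. In Irf8KO cMoPs 64 fell and 32 rose (median -0.44, adjusted p = 0.00133, and adjusted p = 0.134 with an estimated correlation), and in Irf8KO MDPs 54 fell and 33 rose (median -0.21, adjusted p = 0.0568). These medians turned to 0.079 and 0.14 without the filter on dim probes.

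At 2-fold or more, 233 genes were higher both with C/EBPalpha and in Irf8KO cMoPs where 40.2 would be shared by independent sets of the 11206 genes tested in both systems (Fisher's exact test, two-sided, adjusted p = 5.2e-130), and 147 were higher with C/EBPalpha and in Irf8KO MDPs against 29.9 (adjusted p = 1.29e-67). Genes higher with C/EBPalpha but lower in Irf8KO cells were also shared more often, 53 in cMoPs against 28.8 (adjusted p = 1.39e-05) and 43 in MDPs against 23.5 (adjusted p = 0.000124). Over all called genes, without the fold threshold, this turned round, with 460 in cMoPs against 1090 (adjusted p = 3.57e-186) and 552 in MDPs against 1010 (adjusted p = 3.92e-101). Genes higher with C/EBPalpha and in Irf8KO cells stayed more frequent there, 1518 in cMoPs against 773 and 1336 in MDPs against 771. Genes higher with IRF8 and lower in Irf8KO cells numbered 72 in cMoPs against 8.8 (adjusted p = 4.28e-46) and 49 in MDPs against 7.17 (adjusted p = 2.8e-27). Genes higher with IRF8 and also higher in Irf8KO cells numbered 43 in cMoPs against 12.3 (adjusted p = 7.32e-13) and 45 in MDPs against 9.14 (adjusted p = 4.29e-19). Fisher's exact test, here and for the 2 knockouts, counts genes as independent. Its p values do not measure variation between arrays.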

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

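The tests of the sex of the animals and of other cells in the MDP sorts were chosen only after those results were seen. Each value below came from a test of the difference between groups, or was signal in probes outside the comparisons because they match no gene symbol.

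The Irf8KO effect differed between cMoPs and MDPs for 2980 genes. The neutrophil genes S100a9 and Wfdc21 differed by 5.20 and 3.04, and Ltf, Camp and Ngp by 5.21, 4.45 and 3.62 as measured, sizes without weight because Ltf and Ngp were detected in neither MDP group and Camp not in Irf8KO MDPs, and Mogat2 and the granulocyte factor gene Cebpe by 2.48 and 2.39. Among primary granule genes Serpinb1a differed by 0.94, Gstm1 by 0.58, Ms4a3 by 0.52 and Prtn3 by 0.39, the last falling to 0.17 by array median (adjusted p = 0.273). The integrin gene Itgb7 differed by -3.44, S100a4 by -3.27, Plxnb2 by -3.11 and Cox6a2 by -3.02. Among monocyte genes Cx3cr1 differed by -2.87, Irf5 by -2.34, Slc11a1 by -1.72 and Klf4 by -1.36. The MHC class II genes Cd74, H2-DMa, H2-Ob and H2-Ab1 differed by 1.27, -0.94, -0.65 and -0.22. The calls of Cd74 and H2-Ab1 ended under quantile normalization (adjusted p = 0.0521 and 0.113), that of H2-Ob ended without the filter on dim probes (adjusted p = 0.0596), and Cd74, not detected in Irf8KO MDPs, fell to 0.33 under normexp (adjusted p = 0.0986). Irf8 differed by -0.93 and Cebpa by 0.45.

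List medians of the same difference were 1.32 for late neutrophil genes, 0.32 for primary granule genes, 2.23 for basophil, mast cell and eosinophil genes, 0.73 for erythroid genes and 0.22 for interferon-stimulated genes. With dim values raised to the faintest detected signal the basophil, erythroid and interferon-stimulated medians were 1.78, 0.52 and 0.067, and the last list no longer passed (adjusted p = 0.0624). The medians were -0.52 for monocyte and macrophage genes and -0.24 for cell cycle genes. With an estimated correlation only the basophil list passed, and with dim values raised as well it did not (adjusted p = 0.052). In 32Dcl.3 cells the interaction of IRF8 and C/EBPalpha passed for 7429 genes, with list medians of -1.63 for late neutrophil genes, -1.09 for primary granule genes, -1.35 for cell cycle genes and 0.42 for immediate early and heat shock genes. Of these lists, only the late neutrophil and cell cycle ones passed with an estimated correlation. The immediate early call also ended with the deposited series values.

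Probes without a gene symbol also changed at least 2-fold. They numbered 433 in Irf8KO MDPs (241 higher, 192 lower, of 9352 tested) and 501 in Irf8KO cMoPs (342 higher, 159 lower). With C/EBPalpha they numbered 3198 (2061 higher, 1137 lower, of 14334 tested) and with IRF8 433 (314 higher, 119 lower).

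Late neutrophil genes rose in Irf8KO cMoPs by a median of 2.65 (adjusted p = 0.169 with an estimated correlation), and 3 explanations were tested. The scaling of the arrays was excluded, since the lowest median under any scaling was 1.94. The prediction of more C/EBPalpha-dependent transcription without Irf8 was met. The 104 measured genes raised by C/EBPalpha in 32Dcl.3 cells and outside the neutrophil lists had a median of 0.92 (75 rose and 14 fell, camera p = 0.00199 with an estimated correlation). Genes of mature neutrophils were not taken out of this set. Neutrophils among the sorted cells could therefore raise it too, and the test cannot decide between them. Mature neutrophils among the sorted Irf8KO cMoPs are not excluded: of 20 genes of mature neutrophils 10 were measured, 3 of them also in another list, and 9 rose (median of the 10 0.95), such as G0s2 by 2.56, while the other 10 were not well above background on both arrays of any group, which an absence of such cells would also give. The median of the mature neutrophil genes met neither the limit set beforehand for this explanation nor the limit set against it. Its difference from the late neutrophil median was 1.70 (permutation p = 0.0893 over genes, two-sided). That test does not decide, because neither explanation predicts the size of the difference. C/EBPalpha-dependent transcription and mature neutrophils therefore cannot be told apart.

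Basophil and erythroid genes moved down and B and T cell genes up in Irf8KO MDPs, in list calls that were lost with an estimated correlation (adjusted p = 0.163 for basophil genes and 0.32 for the others), the erythroid median turning to 0.11 among genes detected on all 8 arrays. A single change in the share of all other cells would move these genes 1 way, but Prg2 was at least 32.7-fold lower and Il7r at least 9.58-fold higher, and 19 of 24 basophil and erythroid genes fell while 5 of 7 B cell and 7 of 12 T and NK cell genes rose. The difference of the medians, 2.77 (permutation p = 0.0003, two-sided), restates the pattern from which the groups were formed and carries no weight. A different mix of other cells in each sort remains possible, as 19 of the 24 basophil and erythroid genes fell. An effect of Irf8 on these genes inside MDPs could give the same counts.

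DNA of another mouse strain beside the targeted Irf8 gene could add changes near it that do not come from the loss of Irf8. Among the 20 measured genes beside Irf8, 15 were called in Irf8KO cMoPs and 14 in Irf8KO MDPs. Their median absolute change of 0.34 in cMoPs was at percentile 89 of 11559 windows of neighbouring genes, and that of 0.28 in MDPs at percentile 82.3. The largest changes were Crispld2 at 1.53 in MDPs and Zfpm1 at -1.44 in cMoPs. This explanation stays open.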

How the results depend on the processing

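The 75th percentile over detected probes, all probes, limma treat and raised dim values were added after the data were seen. A gene, list or set is called the same when the direction of its test and the side of the 0.05 threshold were kept, stronger or weaker when only the side changed, and reversed when the direction changed in a call that passed. A direction that changed where the call had not passed was counted as the same, and 7 such list results passed the other way, all in WT cMoPs against WT MDPs. The sign of a list or set median is not part of this, and a count is the same within 1.5-fold. Over all settings, 321 counts and medians of gene sets stayed the same, 22 moved and 11 became stronger. Of values of named genes that are reported 12803 stayed the same, 156 became weaker and 58 reversed, and of gene lists 3432 stayed the same, 57 became stronger, 56 weaker and 1 reversed. Of 900 list medians under another scaling 108 had the other sign, 9 of them in lists that passed, such as granulocyte factors in Irf8KO cMoPs (0.29 to -0.023). Of 81 lists that passed, 54 had a median that moved more than 1.5-fold or changed sign under some scaling. For both factors against IRF8, for example, interferon-stimulated genes went from 0.75 to 0.054 and lysosomal genes from 0.88 to 0.19.

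Most reversals were in WT cMoPs against WT MDPs with the deposited series values. By construction these scale the MDP and cMoP columns separately, which moved the median of all genes to 2.19. The granulocyte genes Mpo, Ctsg, Serpinb1a, Gfi1, Runx1 and Cebpe became 1.11, 1.68, 1.71, 2.09, 2.11 and 2.26. Cebpa became 2.36 and Irf8 2.04, and the monocyte gene Nr4a1 1.37. The antigen presentation genes Ccr7, H2-Oa, H2-Ob and H2-Eb1 became 0.070, 0.72, 0.88 and 0.91, and Irf7, Irf3, Irf1 and the interferon-stimulated Oasl2 became 1.37, 1.69, 1.76 and 0.30. The lysosomal genes Lgmn, Ctsf, Ctsd and Man2b1 became 0.43, 1.23, 1.46 and 1.58, the stem genes Sox4, Meis1 and Eng 0.58, 0.80 and 0.92, and the cell cycle genes Mcm6, Ccnb1 and E2f1 1.36, 1.47 and 1.47. The lymphoid genes Blnk, Ccl5, Thy1, Lck and Klrd1 became 0.69, 0.18, 0.79, 0.94 and 1.11, Car2 1.15, and the platelet genes Itga2b, Vwf and Gp9 0.35, 0.74 and 1.16. The stress genes Jund, Dusp2, Hsp90aa1 and Dnajb1 became 1.30, 1.37, 1.53 and 1.66.

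In the same comparison Cebpa became 0.12 under quantile normalization, 0.14 under normexp and 0.14 with the percentile over detected probes. Ctsg became 0.33 under quantile normalization and 0.28 under normexp, Cebpe 0.062 under quantile normalization and 0.045 with the percentile over detected probes, and Irf8 and Mpo 0.099 and 0.059 under normexp. The median of all genes was -0.80 by array median, -0.20 under quantile normalization and -0.15 under normexp.

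In 32Dcl.3 cells with C/EBPalpha alone, Cd79b became -0.085 by array median, H2-Aa -0.027 under normexp and -0.29 with the deposited series values, and H2-Ab1 -0.63 with the latter, these H2 genes being detected in neither group. For both factors against IRF8, Thy1 became -0.018 by array median and -0.011 under normexp, and Ear1, detected in neither group, -0.038 under normexp and -0.31 with the deposited series values. The interaction term of Ccr2, not detected with empty vectors, became 0.23 under normexp. The erythroid list in Irf8KO MDPs became 0.11 among genes well above background on all 8 arrays (adjusted p = 0.557), where fewer of its genes were left. The cause was not tested for the other reversals.

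The IRF8-raised set in Irf8KO MDPs (median -0.21) passed the threshold in 5 settings, with a median of -0.23 under quantile normalization, -0.11 under normexp, -0.22 in eBayes without trend and with all 16 arrays, and -0.20 with the percentile over detected probes. Leaving out single arrays gave medians from -0.23 to -0.19, and the set passed in 6 of those 16 fits. Without the filter on dim probes the medians of this set turned to 0.14 in MDPs and 0.079 in cMoPs.

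Counts of genes depended on the threshold. At 2-fold the counts were 798 in Irf8KO MDPs, 1021 in Irf8KO cMoPs, 490 for their difference, 3006 for WT cMoPs against MDPs, 3125 for C/EBPalpha, 680 for IRF8, 2124 for both factors against C/EBPalpha, 4015 against IRF8, 5108 against empty vectors and 1365 for the interaction. With limma treat at 1.2-fold they were 1883 in Irf8KO MDPs, 2531 in Irf8KO cMoPs, 815 for the difference, 1782 for IRF8, 5786 for both factors against C/EBPalpha and 3559 for the interaction. With all probes they were 16315 for WT cMoPs against MDPs, 19161 for C/EBPalpha, 17467, 21046 and 21696 for both factors against C/EBPalpha, IRF8 and empty vectors, and 12147 for the interaction. With the replicate block the counts were 6333 in Irf8KO MDPs, 6614 in Irf8KO cMoPs and 10492 for C/EBPalpha. Leaving out single arrays gave 5369 to 5846 in Irf8KO MDPs and 5232 to 6856 in Irf8KO cMoPs.

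The share of called genes that were higher moved with scaling. By array median it went from 44.4 to 28.6% in Irf8KO MDPs, from 42.4 to 13.4% in Irf8KO cMoPs, from 46.6 to 11.8% for their difference, from 40.2 to 25.2% for C/EBPalpha and from 47.2 to 59.2% for IRF8. For both factors it went from 47.6 to 20.3% against C/EBPalpha, from 43.9 to 16.1% against IRF8 and from 44.9 to 22% against empty vectors, and for the interaction from 42.7 to 9.27%. For WT cMoPs against MDPs it was 20.1%, and 32.7% under quantile normalization, 32.9% under normexp, 99.6% with the deposited series values, 46.9% with the percentile over detected probes and 35% with all probes. With that percentile it was 52.9% for C/EBPalpha, 59.1 and 56.8% for both factors against IRF8 and empty vectors, and 54.2% for the interaction. Without the filter on dim probes it was 56% for C/EBPalpha and 60.7 and 61.7% for both factors against IRF8 and empty vectors, and with all probes 55.8% for both against IRF8. At 2-fold it was 57.5% in Irf8KO MDPs, 56.9% in Irf8KO cMoPs and 70% for IRF8, and with treat 67.5% for IRF8. The cause was not tested, except that array-median scaling shifts all genes of a comparison by a constant.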

Other observations

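Sex tests were chosen only after that result was seen, and the lists below after the other results but before testing. The p values of these lists were adjusted over 60 tests.

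Genes of ribosome production in the nucleolus fell in both knockouts, 13 of 15 in Irf8KO MDPs with 1 rising (median -0.37) and 14 of 15 in Irf8KO cMoPs (median -0.38). Fbl, a ribosomal RNA methyltransferase gene, changed by -0.55 ± 0.037 and -0.53 ± 0.037 (SE, 2 arrays per group). All 15 fell with C/EBPalpha (median -1.76) and with both factors against empty vectors (median -2.22), with Dkc1, a pseudouridine synthase gene, at -2.19 ± 0.072 and -3.61 ± 0.072. With IRF8 alone 13 of 15 fell (median -0.25). Each of these passed limma's camera (adjusted p = 1.7e-05 to 0.000156), and each was lost with an estimated correlation (adjusted p = 0.0882), as was every other list named here.

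NADPH oxidase genes rose with C/EBPalpha, all 6 (median 1.57, adjusted p = 0.000514, and adjusted p = 0.118 with an estimated correlation), Ncf4 by 1.78 ± 0.029 and Cybb at least 18.7-fold. With IRF8 5 of 6 rose (median 0.37, adjusted p = 0.00302, and adjusted p = 0.138 with an estimated correlation), and in Irf8KO cMoPs 4 of 6 rose with a median of 0.29 that turned to -0.025 when arrays were scaled to their median. MHC class I genes had 9 up and 1 down of 12 with IRF8, the peptide editor gene Tapbp at 1.16 ± 0.035 (median 0.48, adjusted p = 7.09e-05, and adjusted p = 0.106 with an estimated correlation), and 8 up and 3 down with C/EBPalpha (median 0.59, adjusted p = 0.00534, and adjusted p = 0.154 with an estimated correlation). In Irf8KO MDPs 7 of the 12 rose and 1 fell (median 0.26, adjusted p = 0.00534, and adjusted p = 0.167 with an estimated correlation). In Irf8KO cMoPs 6 rose and 1 fell (median 0.35, or 0.038 by array median, adjusted p = 0.0032, and adjusted p = 0.154 with an estimated correlation). H2-K1 exceeded these medians, rising by 0.91 ± 0.043 in MDPs and by 1.22 in cMoPs. Cholesterol synthesis genes had 16 down and 1 up of 18 when IRF8 was added to C/EBPalpha, Dhcr7 at -1.23 ± 0.056 (median -0.53, adjusted p = 0.000327, and adjusted p = 0.0882 with an estimated correlation), and 9 down and 2 up in Irf8KO MDPs (median -0.38, or -0.18 under normexp, adjusted p = 0.0217, and adjusted p = 0.167 with an estimated correlation). Glycolysis genes had 11 down and 1 up of 15 in Irf8KO MDPs, Pfkp at -0.49 ± 0.064 (median -0.18, adjusted p = 0.0104, and adjusted p = 0.167 with an estimated correlation). All 8 complement genes rose with both factors against empty vectors, C3 by 2.88 ± 0.030 (median 1.95, or 0.49 under normexp, adjusted p = 0.00394, and adjusted p = 0.129 with an estimated correlation). Cfb, a complement factor gene, was at least 2.78-fold higher in Irf8KO MDPs and at least 5.71-fold higher in Irf8KO cMoPs.

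The MDP arrays and the cMoP arrays differed in sex-linked transcripts. The 2 Xist probes were well above background on 4 of 4 MDP arrays and none of 4 cMoP arrays, and Ddx3y and Eif2s3y the reverse, so 4 of 5 probes followed this pattern, a Uty probe being detected on 1 of 4 cMoP arrays. Female animals for the MDP arrays and male animals for the cMoP arrays could give this, and no label checked here states the sex. Another Uty probe and Kdm5d were detected on no array. A slide-wide difference in brightness was excluded, because the probes went in opposite directions, Xist being at least 12.1-fold lower and Eif2s3y and Ddx3y at least 47.7-fold and 22.3-fold higher in WT cMoPs than in WT MDPs. The differences as measured, 5.38 for the mean of the 3 Y-linked probes seen on any array and -5.43 for Xist, were taken against undetected probes and their size carries no weight.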
